A study of Homo sapiens with 36 samples.

How the data were processed

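The series measured chromatin occupancy in SUM149 cells, an established line from an inflammatory, triple-negative breast cancer, by chromatin immunoprecipitation and sequencing (ChIP-seq). The antibodies were against KDM5A, KDM5B, ZBTB7A and H3K4me3, the trimethyl mark on lysine 4 of histone H3 that is found at active promoters. Per the labels' protocols, the chromatin for the 3 proteins was fixed with 2 crosslinking steps and that for H3K4me3 with 1. Cells carried a CRISPR guide against KDM5A, KDM5B or ZBTB7A, or against ROSA26, a safe-harbour locus that serves as the control, and were kept in 0.01% DMSO. ROSA26 cells were also treated for 7 days with 10 µM C70, an inhibitor of the KDM5 demethylases.

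Of 36 samples, 33 had a peak list. The 2 inputs, and the H3K4me3 library of replicate 1 under C70, were not analysed here. Each library was put in its group by its labels, which gave replicate numbers but did not say that replicates came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical. No protein was precipitated from cells carrying its own knockout among the lists used, so the check of each knockout on its targeted protein was not analysed here.

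Per the submitters' processing notes, BWA, MACS2 and DESeq2 were used and the genome build was hg19; versions, settings and the role of each tool are not given in the sources used here. The deposited lists are in the narrowPeak format and were called per sample. For each peak the authors gave a start and an end, a fold enrichment (a ratio over the caller's background), −log10 p and −log10 q values, and a score made from the −log10 q. The lowest −log10 q in the deposited lists lay between 2.00 and 2.04, which corresponds to a q of 0.01. Whether an input served as the background of the peak calling is not given in the sources used here. Read counts were not used here, so the sequencing depth behind each list is unknown. A list from a deeper library or a more efficient precipitation holds more and wider peaks, and the lists held between 11392 and 67931 peaks. The fold, −log10 q and score of a peak belong to its own list. They served to rank or filter peaks, through the lowest −log10 q over the libraries that held a region where several did, and were not used to compare groups.

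Peaks on chromosome Y and on unplaced sequences, 1 to 26 per list, were left out. Overlapping peaks (at least 1 bp) of the libraries compared were merged into regions. A region was gained when both libraries of a group held a peak in it and neither control library did, and lost in the opposite case. Each of the 13 contrasts set a group against the ROSA26 control in DMSO for the same antibody. A comparison of 2 libraries with 2 has 3 splits and cannot reach a two-sided p below 0.33, so gained and lost regions have no test. Their counts are set beside the larger count from the 2 crossed splits, in which each side holds 1 library of each group. The H3K4me3 list under C70 is a lone library, and its values have no replicate check.

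The number of peaks per library and the median covered width per library, over regions called in every library fitted, were compared across the 4 groups of 2 libraries of an antibody. An exact permutation test of the between-group sum of squares on the log2 scale was used, over all 2520 assignments of libraries to groups. It is two-sided by construction and does not say which group differs.

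Covered width in bp was also tested per region with limma, on log2 width without a pseudocount, over the regions called in all 8 fitted libraries of an antibody and with all 4 groups in 1 fit (4 residual degrees of freedom). Each library was centred on its median log2 width, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A width change given per region is relative to the shift of the whole library, which is given once per contrast.

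Co-occupancy is the share of regions called in both control libraries of 1 antibody that overlap a region called in both control libraries of another. The same share was taken from 100 shuffles of region positions within chromosomes. Throughout, a protein or mark is said to be present in control cells only where both of its control libraries called the region. A peak in 1 of them counts as absent. Contrasts that share the control libraries were compared through the correlation and covariance of width changes across regions and through shared gained or lost regions. These were set beside 20 simulations of unchanged groups against the same controls and beside the overlap of independent lists. The overlap of independent lists was taken over all regions of the antibody. It is too low a benchmark, since only regions in neither control list can be gained and only regions in both can be lost. The simulated lists differ in length from the observed ones, so shared regions are given as a share of the shorter list, which still depends on its length.

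Regions named in the text were chosen by a rule fixed before the data were examined. For width, these were the largest changes past the threshold whose libraries did not overlap between groups. Where no region passed, those with the smallest p were taken and are said not to pass. For gain and loss, these were the regions with the highest minimum −log10 q over the libraries of the group that held the peaks. At most 3 regions were named per contrast and direction, since no annotation of hg19 was used here; regions are given by 1-based hg19 coordinates, without genes. The planned comparisons of preset gene lists, by promoter width and by promoter occupancy, needed that annotation and were not run.

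Alternatives fixed before the data were examined were a minimum −log10 q of 5, an overlap of 50% of the shorter peak, equal peak numbers per antibody, no centring, the span of a region, regions called in at least 50% of the libraries (with 200 bp added to each width), a fit of only the 2 groups compared, the replicate number as a block, and each library left out in turn. Equal peak numbers kept the strongest 19726 peaks of each H3K4me3 list, 17784 of each KDM5A list, 11392 of each KDM5B list and 35919 of each ZBTB7A list. Cyclic loess normalization of widths, and leaving out regions within 2 Mb of the largest peak-free stretch of each chromosome, were added after seeing the data. So was the similarity of width changes with a different control library for each contrast of a pair, averaged over both pairings. So was a comparison of H3K4me3 regions with and without a protein at the same control width, which took the difference within 10 width classes, each holding equal numbers of the regions with none of the 3 proteins, and averaged the classes. Kept regions in the same width range are those between the lower and upper quartiles of the width of gained regions. This comparison was added after seeing the data too, with its bound set before its result only for each protein in its own knockout.

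Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, bedtools 2.31.1, and R 4.3.3 with limma 3.58.1 were used. Interval counts were checked against bedtools and were equal in 4 of 4 comparisons. In a simulated pair of H3K4me3 lists, 200 of 200 planted gains and 100 of 100 planted losses were recovered. The width test was tested on simulated data with 50 planted changes per size. On the 18348 H3K4me3 regions it recovered 10% of changes of 0.25 on the log2 scale, 78% of 0.5, 94% of 1 and 98% of 2, with 3 false calls. For changes of 1 on the log2 scale it recovered 70% over 13694 KDM5A regions, 14% over 6031 KDM5B regions and 28% over 28103 ZBTB7A regions, with 7, 4 and 6 false calls.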

Results

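KDM5A and KDM5B are demethylases that remove methyl groups from lysine 4 of histone H3, and ZBTB7A is a zinc-finger transcription factor. To ask where these proteins sit in SUM149 breast cancer cells, and what happens to their sites and to H3K4me3 when 1 of them is lost or when the KDM5 enzymes are inhibited, 33 ChIP-seq peak lists were compared. Every group had 2 libraries except H3K4me3 under C70, which had 1. Sequencing depth is unknown. The control (ROSA26 knockout, DMSO) lists held 20405 ± 960 peaks for H3K4me3, 25218 ± 4690 for KDM5A, 34099 ± 7397 for KDM5B and 46601 ± 15106 for ZBTB7A (mean ± SD, n = 2 each). Replicates of H3K4me3 shared 86.9% to 88.2% of the regions called in either library of a group. The shared part was 63.2% to 75.3% for KDM5A, 56.2% to 73.5% for ZBTB7A and 34.0% to 62.1% for KDM5B, whose lowest values belonged to the KDM5A and ZBTB7A knockouts (37.5% and 34.0%). In control cells it was 58.7% for KDM5B and 56.2% for ZBTB7A.

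**Figure D1:**
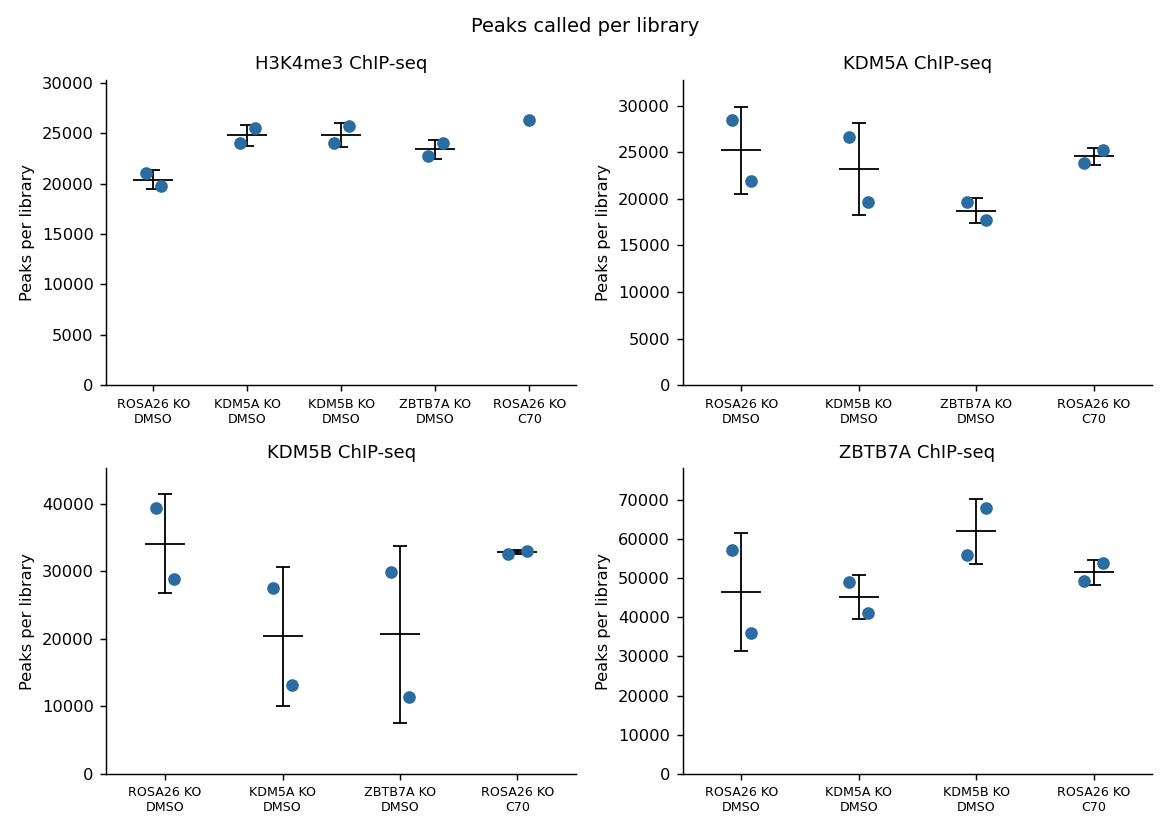
Peaks per library (vertical axis, number of peaks) for each antibody, by knockout and treatment. Points are libraries, and bars are the mean and SD over 2 libraries. The 2 KDM5B libraries of the KDM5A knockout (27577 and 13098 peaks) and of the ZBTB7A knockout (29957 and 11392 peaks) lie far apart.

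In control cells each of the 3 proteins was present at most H3K4me3 regions, while KDM5B and ZBTB7A were also called at many regions without the mark. Of 18978 H3K4me3 regions called in both control libraries, 83.5% overlapped a KDM5A region, 79.3% a ZBTB7A region and 62.4% a KDM5B region. All 3 proteins were present at 10433 of them (55.0%), whose median width was 2190 bp. None of the 3 was present at 1533 (8.08%), with a median width of 628 bp. KDM5A lay mostly at H3K4me3: 82.8% of its 19738 regions overlapped the mark, against 51.7% of 24772 KDM5B regions and 47.0% of 32579 ZBTB7A regions. ZBTB7A was present at 83.6% of KDM5A regions and at 71.5% of KDM5B regions, and 63.2% of ZBTB7A regions overlapped KDM5A or KDM5B. KDM5A and KDM5B overlapped at 70.5% of KDM5A regions and 59.4% of KDM5B regions. Shuffled positions gave 1.67% to 3.84% for these pairs. The shuffles placed regions anywhere along a chromosome, so they are a low benchmark. The shares differed between replicates by an SD of 2.09 to 9.90 percentage points, so an order of shares closer than that is not resolved.

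After knockout of any of the 3 proteins many narrow H3K4me3 regions were called that neither control list held, and few control regions were missing. The KDM5A knockout gained 2359 regions and lost 16, the KDM5B knockout gained 2309 and lost 6, and the ZBTB7A knockout gained 1467 and lost 34. The larger counts of the crossed splits were 229, 233 and 389, so each gain exceeded the replicate spread in the deposited lists. Gained regions were narrow, with medians of 474, 486 and 473 bp, against 2101, 2013 and 1953 bp for regions kept in each contrast. Their median lowest −log10 q, over the libraries that held them, was 6.75, 6.98 and 6.19, against 382, 382 and 351 for kept regions. The deposited lists grew from 20405 ± 960 peaks in control cells to 24795 ± 1003, 24868 ± 1205 and 23405 ± 919 (n = 2 each), which did not reach the threshold (exact permutation test, p = 0.0667). With equal peak numbers per list the gains came to 363, 268 and 346 and the losses to 179, 127 and 183, so the direction held at much smaller counts. No crossed splits were counted at equal peak numbers, so whether these smaller gains exceed the replicate spread is not known.

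The gained regions overlapped the proteins of control cells less often than kept regions did, but most of that difference was absent beside other narrow regions. KDM5A was present at 19.2%, 19.9% and 17.5% of the regions gained in the KDM5A, KDM5B and ZBTB7A knockouts, against 84.0%, 84.0% and 84.3% of all kept regions and 30.8%, 31.2% and 33.2% of kept regions in the same width range. KDM5B was present at 32.3%, 32.9% and 31.6% of gained regions, against 63.1%, 63.0% and 63.1% of all kept regions and 34.2%, 35.8% and 35.3% of those in the same width range. ZBTB7A was present at 46.5%, 52.9% and 49.1%, against 79.7%, 79.6% and 79.7% of all kept regions and 47.0%, 43.8% and 43.0% of those in the same width range, so in the KDM5B and ZBTB7A knockouts the direction turned. The larger sides of the crossed splits, whose regions were also narrow, had KDM5A at 24.9%, 23.6% and 27.2%, KDM5B at 34.1%, 38.2% and 41.9%, and ZBTB7A at 68.6%, 67.0% and 66.8%. Among the strongest gains of the KDM5A knockout were 80577576 to 80578068 on chromosome 6, with −log10 q of 52.4 and 57.3 in its 2 libraries, and 177609557 to 177609807 on chromosome 3, with 64.1 and 51.2. At neither region had any of the 3 proteins been called in both of its control libraries. In the KDM5B knockout they were 81174621 to 81174916 on chromosome 17 (40.9 and 47.8), where ZBTB7A was present in control cells, and 22804 to 23176 on chromosome 8 (35.8 and 48.2), where all 3 proteins were. In the ZBTB7A knockout they were 55795177 to 55796292 on chromosome 19 (54.4 and 146) and 31021321 to 31022447 on chromosome 16 (43.1 and 222), without any of the 3 proteins. A region on chromosome 17 from about 25539172 to 25539445 was among the 3 strongest gains in every knockout, and it lies within 2 Mb of the largest peak-free stretch of that chromosome. Of the losses, 56438346 to 56438624 on chromosome 7 was among the 3 strongest in every knockout, and it lies within 2 Mb of such a stretch as well.

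**Figure D2:**
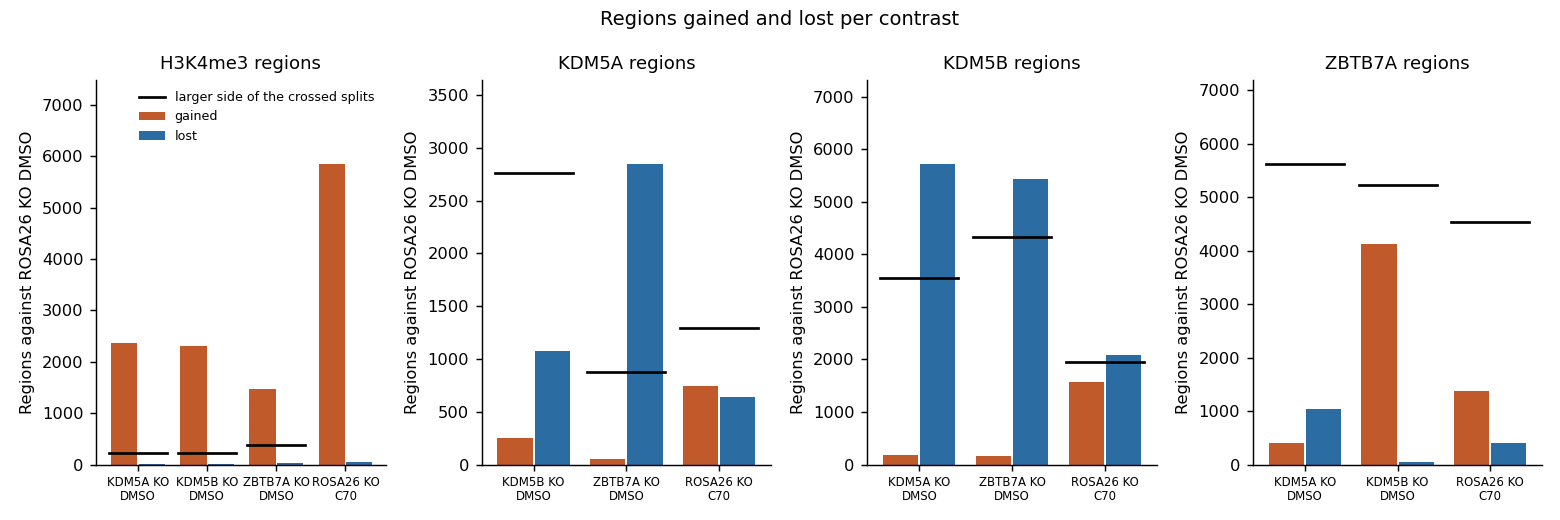
Regions gained (orange) and lost (blue) against the control (vertical axis, number of regions) for each antibody and contrast. Black lines mark the larger count from the crossed splits, a measure of replicate spread that shorter lists of the whole control group would not raise. H3K4me3 under C70 has 1 library and no such line. The H3K4me3 gains of 2359, 2309 and 1467 lie above theirs.

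H3K4me3 regions called in every library were also broader in the knockouts. Over 18348 such regions the median width was 1760 ± 49.5 bp in control cells. It was 2063 ± 51.6 bp in the KDM5A knockout, 1973 ± 65.4 bp in the KDM5B knockout and 1893 ± 48.1 bp in the ZBTB7A knockout (mean ± SD, n = 2 each). The groups differed (exact permutation test, p = 0.00952, the smallest these libraries can give), and both libraries of each knockout lay above both control libraries. The whole libraries were shifted by 0.23, 0.16 and 0.11 on the log2 scale. Beyond that shift, limma found 141 wider and 12 narrower regions in the KDM5A knockout, 122 and 1 in the KDM5B knockout, and 152 and 10 in the ZBTB7A knockout, at an adjusted p under 0.05. The median change of the wider regions was 0.90, 0.91 and 0.88 on the log2 scale.

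The same region of the X chromosome, 143810425 to 143814421, broadened most in all 3 knockouts. It covered 410 and 424 bp in the control libraries, 2419 and 3072 bp in the KDM5A knockout (log2 change 2.48 ± 0.16 SE, adjusted p = 0.00688), 2465 and 2981 bp in the KDM5B knockout (2.54 ± 0.16, adjusted p = 0.00808) and 1883 and 2548 bp in the ZBTB7A knockout (2.29 ± 0.16, adjusted p = 0.00725), by limma. On chromosome 1, 109750736 to 109752629 went from 305 and 292 bp to 1257 and 1565 bp without KDM5A and to 1406 and 1578 bp without KDM5B (2.00 ± 0.09 and 2.15 ± 0.09). Other regions were among the 3 largest changes of 1 knockout each: 52195563 to 52197117 on chromosome 20 in the KDM5A knockout (2.21 ± 0.30), 90962197 to 90964655 on chromosome 15 in the KDM5B knockout (2.00 ± 0.23), and 58419729 to 58423396 on chromosome 5 (2.11 ± 0.24) and 55936322 to 55938014 on chromosome 18 (2.07 ± 0.26) in the ZBTB7A knockout. Narrowing was smaller. The KDM5A knockout narrowed 139606246 to 139608151 on chromosome 9 from 923 and 891 bp to 460 and 383 bp (-1.34 ± 0.15, limma adjusted p = 0.0308), 128165301 to 128166539 on chromosome 2 (-0.68 ± 0.04) and 373569 to 374853 on chromosome 5 (-0.55 ± 0.06). In the KDM5B knockout 135074332 to 135076333 on chromosome 10 narrowed (-0.40 ± 0.05), the only narrower call there, and 0 remained with the replicate block, without centring, with equal peak numbers or without any 1 knockout library. The ZBTB7A knockout narrowed 61455859 to 61456756 (-0.94 ± 0.08) and 46653431 to 46655161 (-0.88 ± 0.12) on chromosome 20 and 39078618 to 39079199 on chromosome 9 (-0.86 ± 0.09). The counts of changed regions (153, 123 and 162) depended on the fit: a fit of only the 2 groups gave 10, 44 and 21, with 0 narrower in each knockout, and a fit without centring gave 9350, 1730 and 246. Leaving out control replicate 1 gave 585, 573 and 610, and leaving out 1 library of the knockout itself gave as few as 12, 7 and 30; the exact p became 0.0667 without control replicate 2 and 0.0571 without ZBTB7A knockout replicate 2.

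**Figure D3:**
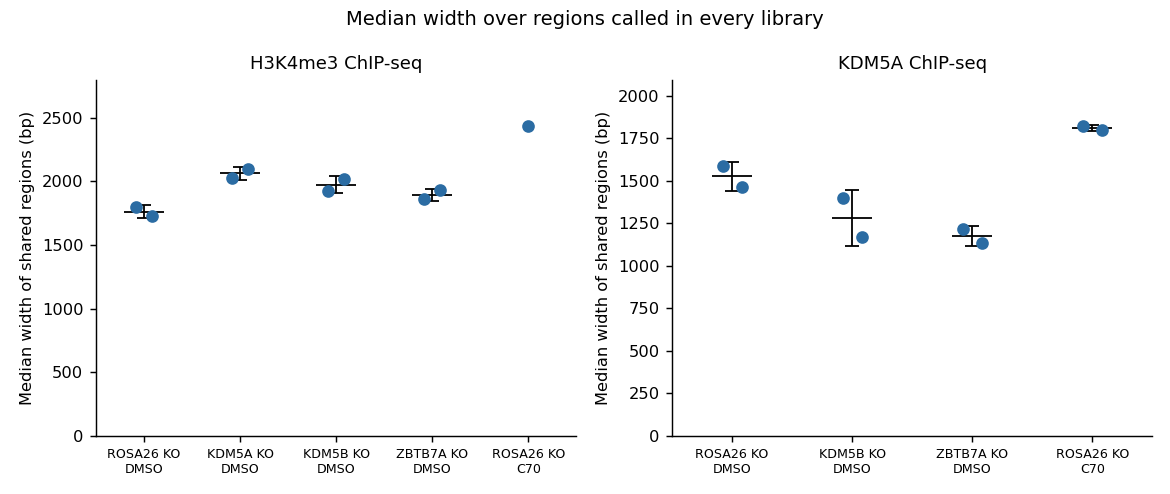
Median covered width (vertical axis, bp) over regions called in every library, for H3K4me3 and KDM5A. Points are libraries and bars are the mean and SD over 2 libraries; the single C70 point for H3K4me3 (2435 bp) and both C70 libraries for KDM5A (1820 and 1795 bp) lie above all other libraries.

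Inhibition with C70 gave the broadest H3K4me3 of all conditions, in a lone library with no replicate check. It held 26370 peaks covering 52.0 Mb, against 34.5 ± 1.54 Mb in control cells, 42.9 ± 1.68 Mb in the KDM5A knockout, 41.4 ± 2.30 Mb in the KDM5B knockout and 38.6 ± 1.67 Mb in the ZBTB7A knockout (n = 2 each). Over 18320 regions called in all 9 libraries the median width was 2435 bp, against 1763 ± 48.1 bp in control cells (n = 2), a shift of 0.47 on the log2 scale (1.38-fold). The region was wider than in both controls at 97.9% of them and narrower than in both at 0.519%. C70 cells gained 5849 regions and lost 58. The gained regions had a median width of 446 bp and overlapped control KDM5A at 18.9%, KDM5B at 33.0% and ZBTB7A at 55.6%, against 24.3%, 29.8% and 36.2% of kept regions in the same width range. The 3 strongest gains were 74094962 to 74097078 on chromosome 10 (−log10 q of 147), where all 3 proteins were present in control cells, 47769024 to 47769493 on chromosome 10 (131), with ZBTB7A, and 94157887 to 94161267 on chromosome 1 (108), with KDM5B and ZBTB7A. The 3 strongest losses were 29086547 to 29086804 on chromosome 16 (104 and 55.7 in the control libraries), 7661124 to 7661390 on chromosome 1 (27.0 and 24.1) and 74358226 to 74358510 on chromosome 15 (23.1 and 11.1). With equal peak numbers the counts were 1162 gained and 485 lost.

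The H3K4me3 changes in the 3 knockouts fell on many of the same regions. Of 2264 regions gained in the KDM5A knockout and 2206 in the KDM5B knockout, counted over all H3K4me3 libraries together, 1401 were shared, which is 63.5% of the shorter list. Independent lists of this length drawn from all 29849 regions would share 167. This benchmark is too low here and below, since only regions absent from both control libraries can be gained. Those libraries held 21508 regions between them. Simulated unchanged groups against the same controls gave shorter lists, of 335 and 331 regions, which shared 25.6% of the shorter one. The ZBTB7A knockout gained 1408, of which 937 (66.5%) were shared with the KDM5A knockout and 912 (64.8%) with the KDM5B knockout (107 and 104 for independent lists, 25.6% and 25.5% simulated). C70 gained 5568 and shared 1623, 1588 and 1026 with the KDM5A, KDM5B and ZBTB7A knockouts (422, 412 and 263 for independent lists). These were 71.7%, 72.0% and 72.9% of the shorter list, against 44.9%, 45.4% and 44.7% simulated. The C70 list is long beside the regions absent from both control libraries, so whether its sharing exceeds that of unrelated lists is not known. Among regions with a width call, 95 were called in both the KDM5A and KDM5B knockouts, 86 in the KDM5A and ZBTB7A knockouts and 79 in the KDM5B and ZBTB7A knockouts. These counts were not compared with unchanged groups. Across the 18348 regions, which are not independent replicates, the width changes correlated with Pearson's r of 0.855, 0.721 and 0.765 for these pairs, against 0.501, 0.499 and 0.500 simulated. The covariances were 0.0548, 0.0448 and 0.0469, against 0.00780, 0.00778 and 0.00778 simulated. With each knockout of a pair measured against a different control library, r was 0.502, 0.380 and 0.415 and the covariance 0.0388, 0.0289 and 0.0310. This setting was chosen after the values above had been seen. It removes the noise of a single control library that both contrasts would share. A deviation common to both control libraries, such as a shortage of weak peaks, stays in both contrasts and was not part of the simulations. For gained regions the part of the shared controls was not separated, since a region shared between 2 lists is absent from both control libraries either way.

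Whether width changes lay where the proteins had been bound depended on the width of the regions compared. H3K4me3 regions that overlapped none of the 3 proteins in control cells (1357 regions) widened relative to their library by 0.15, 0.18 and 0.16 on the log2 scale in the KDM5A, KDM5B and ZBTB7A knockouts. The 15542 regions with KDM5A had median changes of -0.01, -0.02 and -0.02. The difference between bound and unbound regions was -0.17 for KDM5A sites in the KDM5A knockout (-0.14 and -0.18 in its 2 libraries), -0.20 for KDM5B sites in the KDM5B knockout (-0.15 and -0.25) and -0.18 for ZBTB7A sites in the ZBTB7A knockout (-0.13 and -0.22). The control libraries, measured against their own mean, lay at -0.04 and 0.04, which mirror each other by construction. The difference lay further from 0 in each of these knockout libraries. The control values understate the spread of a library that is not part of that mean, and no test was planned. Under C70 it was -0.16 at KDM5A regions. Regions with none of the proteins are narrower, so the same change in bp is larger for them on the log2 scale, and centring keeps the bound regions, which are the majority, near 0. In a comparison at the same control width, chosen after these values had been seen, the differences were 0.09 for KDM5A sites in the KDM5A knockout, 0.04 for KDM5B sites in the KDM5B knockout and 0.07 for ZBTB7A sites in the ZBTB7A knockout. With the width taken from 1 control library and the change measured against the other, they were 0.04 (0.01 to 0.08 over the libraries), 0.01 (-0.02 to 0.04) and 0.02 (-0.01 to 0.04). Under C70 the difference at KDM5A regions became 0.35 at the same width, and 0.27 with the 2 control libraries kept apart in this way, in the lone C70 library.

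In the deposited lists KDM5A regions were lost after loss of ZBTB7A, and those called in every library were narrower. Lower read depth or a less efficient precipitation was not separated from an effect of the knockout. The lists held 18738 ± 1348 peaks (n = 2), and the 4 KDM5A groups did not differ detectably in peak number (exact permutation test, p = 0.352). The ZBTB7A knockout lost 2846 KDM5A regions and gained 52, against 877 in the crossed splits. The lost regions were narrow (median 584 bp against 1619 bp for kept regions) and were less often marked by H3K4me3 (41.0% against 95.1%), and 72.3% of them had ZBTB7A in control cells, against 86.9% of kept regions. The regions of the larger crossed split had H3K4me3 at 25.5% and ZBTB7A at 69.4%. Over 13694 regions called in all KDM5A libraries the median width was 1524 ± 84.5 bp in control cells and 1176 ± 58.0 bp in the ZBTB7A knockout (n = 2 each), a library shift of -0.37 on the log2 scale. Beyond that shift, limma found 19 narrower regions and 0 wider ones. These were led by 69785177 to 69787787 on chromosome 9 (2473 and 2135 bp to 288 and 331 bp, -2.52 ± 0.20, adjusted p = 0.0113), 781695 to 784165 on chromosome 19 (-2.17 ± 0.16) and 46448206 to 46451660 on chromosome 22 (-2.15 ± 0.25). Outside the flanks of peak-free stretches, the strongest lost region by the rule was 72649604 to 72650080 on chromosome 7 (−log10 q of 28.6 and 30.5), which carried H3K4me3 and ZBTB7A. With equal peak numbers the losses came to 739 and the gains to 187. No crossed splits were counted at equal peak numbers, so whether these losses exceed the replicate spread is not known. Of the 19 width calls, 2 remained with the replicate block and 0 in a fit of only the 2 groups. The 19 calls became 0 without either control library or either C70 library, and 179 without ZBTB7A knockout replicate 1.

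After loss of KDM5B, gains and losses of KDM5A regions were within the replicate spread. The KDM5B knockout lost 1079 KDM5A regions and gained 251, below the 2762 of a crossed split, and the median width was 1281 ± 163 bp (n = 2, library shift -0.26). limma called 0 width changes, with 963 of 13694 at an unadjusted p under 0.05. The smallest p belonged to 16973471 to 16974789 on chromosome 1 (-1.40 ± 0.12, adjusted p = 0.0932), which did not pass. The losses of the KDM5B and ZBTB7A knockouts shared 746 regions of 1037 and 2745, which is 71.9% of the shorter list. Independent lists would share 80.3 regions, which is too low a benchmark here too. Simulated lists of 690 and 687 regions shared 37.1%. This sharing was not particular to the 2 knockouts: 513 of the 647 regions lost under C70 (79.3%, 37.6% simulated) were also lost in the ZBTB7A knockout, and 262 (40.5%, 37.4% simulated) in the KDM5B knockout. Leaving out KDM5B knockout replicate 1 gave 96 width calls, and leaving out replicate 2 turned the balance to 3078 gained and 1307 lost.

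KDM5A regions were broader in both C70 libraries than in all other libraries, while their number stayed close to control, at 24571 ± 939 peaks. Their median width was 1807.5 ± 17.7 bp (n = 2), a library shift of 0.25, and the 4 KDM5A groups differed in width (exact permutation test, p = 0.0190). The test does not say which group differs, and the narrower ZBTB7A knockout enters it too. That width p rose to between 0.0571 and 0.0667 without any 1 library of the control, C70 or ZBTB7A knockout groups. C70 gained 749 KDM5A regions and lost 641, both within the 1290 of a crossed split. H3K4me3 marked 44.5% of gained and 8.89% of lost regions in control cells, against 89.0% of kept regions and 15.5% of those of the larger crossed split. Among the strongest were a gain at 195679519 to 195679824 on chromosome 3 (at least 20.3 in both libraries), which carried H3K4me3 in control cells, and a loss at 49196498 to 49197079 on chromosome 20 (24.5 and 19.7), which did not. limma called 0 width changes beyond the shift, with 729 at an unadjusted p under 0.05, and also 0 without centring, with 1926 at that p; 102187813 to 102189721 on chromosome 11 had the smallest p (1.17 ± 0.15, adjusted p = 0.700) and did not pass.

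In the deposited lists, far more KDM5B regions were lost than gained after knockout of KDM5A or ZBTB7A. The imbalance was much smaller with equal peak numbers, as given below. The regions lost differed between the knockouts in how often they carried ZBTB7A. The KDM5A knockout lost 5716 and gained 180, and the ZBTB7A knockout lost 5436 and gained 167. The crossed splits gave 3541 and 4328. Of the regions lost without KDM5A, 53.8% had ZBTB7A in control cells, against 78.7% of kept regions. Of those lost without ZBTB7A, 79.6% had ZBTB7A, against 65.9% of kept regions. The regions of the larger crossed splits had ZBTB7A at 65.4% for the KDM5A knockout and 47.6% for the ZBTB7A knockout. Both lists shared 2441 of 5570 and 5237 regions, which is 46.6% of the shorter list (546 regions for independent lists, too low a benchmark). Simulated lists of 1593 and 1590 regions shared 33.1%. Peak strength was compared within quartiles of control −log10 q. In the KDM5A knockout, KDM5B was lost from 33.2%, 18.4%, 8.47% and 2.10% of regions with ZBTB7A, from the weakest to the strongest quartile, and from 45.6%, 50.1%, 52.0% and 18.2% of those without. In the 2 stronger quartiles this was not particular to ZBTB7A. Loss there was 8.82% and 2.37% with KDM5A against 41.5% and 18.3% without. With H3K4me3 it was 10.1% and 2.44%, against 36.4% and 15.0% without. In the weakest quartile regions with KDM5A or H3K4me3 were lost more often than those without. In the ZBTB7A knockout the differences between regions with and without ZBTB7A were 0.632, -0.873, -3.14 and -0.666 percentage points, so the difference of 8.76 points over all regions was not present within quartiles. Loss in this knockout followed peak strength: 46.9%, 28.0%, 10.9% and 0.650% of regions with ZBTB7A were lost, from the weakest to the strongest quartile. The quartiles were examined after the overall shares had been seen, and no test was run on the difference between the knockouts.

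**Figure D4:**
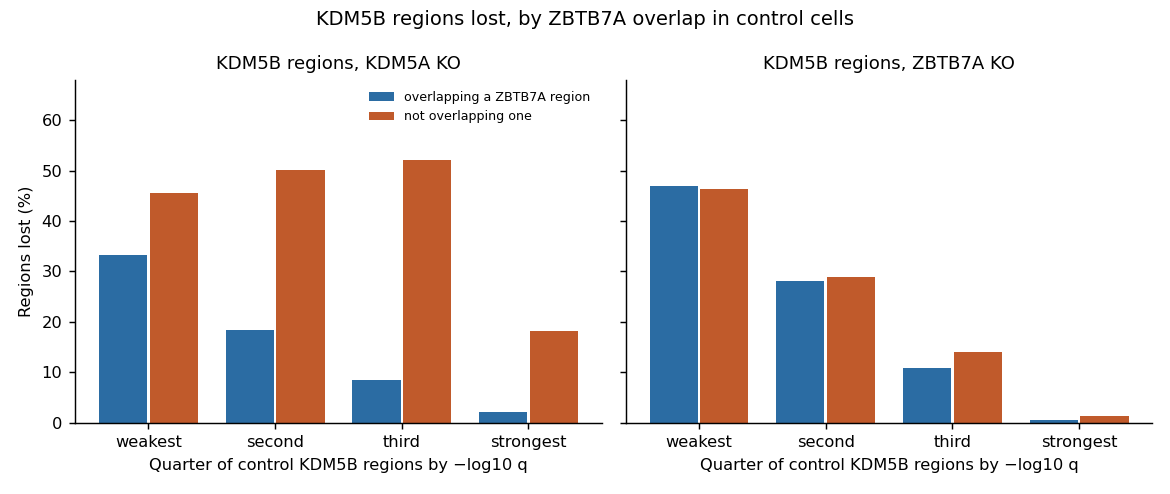
Share of control KDM5B regions lost (vertical axis, %) in the KDM5A and ZBTB7A knockouts, by quartile of control −log10 q, for regions with (blue) and without (orange) ZBTB7A in control cells. In the KDM5A knockout the share is higher without ZBTB7A in every quartile, 52.0% against 8.47% in the third; in the ZBTB7A knockout the differences are 0.632, -0.873, -3.14 and -0.666 percentage points.

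Among the strongest KDM5B regions lost in the KDM5A knockout were 75243019 to 75243538 on chromosome 17 (80.7 and 61.0) and 77153525 to 77154732 on chromosome 18 (72.6 and 58.9), both with H3K4me3, KDM5A and ZBTB7A in control cells. In the ZBTB7A knockout they were 113260715 to 113261035 on chromosome 13 (36.9 and 33.9), with H3K4me3, and 172133959 to 172134537 on chromosome 5 (48.6 and 32.9), without the mark. The ZBTB7A knockout also narrowed KDM5B regions: of 6031 called in all libraries, limma found 30 narrower and 0 wider beyond a library shift of -0.56. The leading ones were 69109569 to 69114034 on chromosome 15 (3675 and 3829 bp to 606 and 257 bp, -2.69 ± 0.37, adjusted p = 0.00900), 245316306 to 245320844 on chromosome 1 (-2.66 ± 0.35) and 35292798 to 35296349 on chromosome 17 (-2.55 ± 0.45). In the KDM5A knockout (library shift -0.48) 0 regions passed in limma and 551 had an unadjusted p under 0.05; 29562521 to 29565434 on chromosome 1 (-2.18 ± 0.31, adjusted p = 0.0584) did not pass. The groups did not differ detectably in peak number (exact p = 0.257) or width (exact p = 0.190), and replicate 2 of each knockout had a much shorter list than replicate 1. With equal peak numbers the KDM5A knockout gained 1514 and lost 1770 and the ZBTB7A knockout gained 676 and lost 866; the 30 calls became 0 without either control library and 125 without ZBTB7A knockout replicate 1.

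Under C70 the KDM5B regions gained were within the replicate spread and those lost only just above it. C70 cells lost 2090 KDM5B regions and gained 1567, against 1950 in a crossed split, with 32820 ± 321 peaks in all (n = 2). Lost regions were rarely marked by H3K4me3 (8.09%) or shared with KDM5A (8.71%) or ZBTB7A (26.9%) in control cells. Gained regions carried H3K4me3 at 56.1%, KDM5A at 48.7% and ZBTB7A at 66.3%, kept regions at 62.1%, 71.2% and 80.7%, and the regions of the larger crossed split at 23.7%, 22.8% and 49.6%. Outside the flanks of peak-free stretches the strongest loss was 21641834 to 21642207 on chromosome 8 (51.0 and 53.2), with KDM5B alone. Of the regions lost under C70, 1244 of 2074 (60.0%) were also lost in the KDM5A knockout. Independent lists would share 216, too low a benchmark, and simulated lists of 1593 and 1596 regions shared 33.1%. The ZBTB7A knockout had lost 696 of the regions lost under C70 (33.6%). Independent lists would share 203 and simulated lists shared 33.2%, so no excess over unchanged groups was seen there. limma called 0 width changes, with 276 at an unadjusted p under 0.05, and the library shift was 0.06. With equal peak numbers 1304 regions were lost and 1437 gained, so the balance between gains and losses turned.

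Gains and losses of ZBTB7A regions stayed below the replicate spread in all 3 contrasts. The 2 control lists held 57282 and 35919 peaks. The KDM5B knockout gained 4136 regions and lost 56 (5229 in a crossed split), the KDM5A knockout gained 396 and lost 1038 (5621), and C70 gained 1370 and lost 408 (4538). The regions gained in the KDM5B knockout had KDM5A at 4.67%, KDM5B at 6.53% and H3K4me3 at 6.12%, close to the regions of the larger crossed split (6.71%, 8.19% and 10.2%), while the wider kept regions had 51.1%, 52.2% and 47.8%. The strongest was 70602288 to 70602602 on chromosome 8 (71.4 and 102), a region that was also the strongest KDM5B gain of the ZBTB7A knockout (70602293 to 70602536, 92.9 and 57.3). Neither peak number (exact p = 0.410) nor width (exact p = 0.448) differed detectably over the 4 groups, and without control replicate 1 the width p was 0.0190. Library shifts were 0.30 in the KDM5B knockout, -0.14 in the KDM5A knockout and 0.16 under C70. Of 28103 regions called in all libraries, limma found 2 narrower in the KDM5A knockout, 6936828 to 6939072 on chromosome 12 (2245 and 1513 bp to 229 and 239 bp, -2.83 ± 0.18, adjusted p = 0.000719) and 46706545 to 46708085 on chromosome 1 (-1.86 ± 0.19). C70 narrowed 1, 23493430 to 23494720 on chromosome 19 (-2.29 ± 0.23, limma adjusted p = 0.0426), and the KDM5B knockout 0, with 1190 at an unadjusted p under 0.05. The C70 call was lost without any 1 of the 8 libraries, and with equal peak numbers the KDM5B knockout gained 1137 and lost 701.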

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

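Cyclic loess normalization, the exclusion of regions near peak-free stretches, the comparison of bound regions at the same control width, the separate control libraries for similarity and the comparison of gained with kept regions in the same width range were chosen only after the data had been seen. The other settings below were fixed before the data were examined. The directions of H3K4me3 gain, loss and width held throughout, but not that of the change at bound regions: in each knockout and under C70 more regions were gained than lost, and in each width fit of each knockout more regions were wider than narrower. The counts themselves moved widely, and read depth, which limits how many weak peaks each list holds, is unknown. For KDM5A, KDM5B and ZBTB7A the short lists of single replicates limited what was resolved. The cause of the changes below was not tested unless stated.

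Equal peak numbers gave 363 gained and 179 lost H3K4me3 regions in the KDM5A knockout, 268 and 127 in the KDM5B knockout, 346 and 183 in the ZBTB7A knockout and 1162 and 485 under C70. For KDM5A they gave 610 lost in the KDM5B knockout, 187 gained and 739 lost in the ZBTB7A knockout and 319 lost under C70. For KDM5B they gave 1514 gained and 1770 lost in the KDM5A knockout, 676 and 866 in the ZBTB7A knockout and 1437 gained and 1304 lost under C70, where the balance turned to gains. For ZBTB7A, 829 were gained in the KDM5A knockout, 1137 gained and 701 lost in the KDM5B knockout and 973 lost under C70. The setting brings gains and losses closer by its construction, since every list then has the same length. Width calls were 76 for H3K4me3 in the KDM5B knockout, 22 for KDM5B in the KDM5A knockout, 4 for KDM5B under C70, and 0 for ZBTB7A under C70 and in the KDM5A knockout.

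With a minimum −log10 q of 5, gained KDM5A regions numbered 140 in the KDM5B knockout and 25 in the ZBTB7A knockout, KDM5A regions lost under C70 421, and ZBTB7A regions lost in the KDM5B knockout 26. The share overlapping KDM5B was then 52.5% of H3K4me3, 61.5% of KDM5A and 44.8% of ZBTB7A regions, and 54.4% of KDM5B regions overlapped KDM5A. An overlap of 50% of the shorter peak moved no count by over 1.5 times. Without the flanks of peak-free stretches the H3K4me3 regions lost in the KDM5B knockout numbered 3.

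Width calls for H3K4me3 in the KDM5A, KDM5B and ZBTB7A knockouts were 9350, 1730 and 246 without centring, 10, 44 and 21 with only the 2 groups, and 1243, 1079 and 865 over regions called in at least 50% of the libraries, where more regions were tested. KDM5A calls in the ZBTB7A knockout were 489 without centring, 0 with only the 2 groups, 522 over regions in at least 50% of libraries, 37 with the span and 12 with cyclic loess. For KDM5A, the wider set of regions also gave 54 calls under C70 and 105 in the KDM5B knockout, where the span gave 4. KDM5B calls in the ZBTB7A knockout were 9 without centring, 0 over the wider set, 19 with the span and 9 with cyclic loess, and in the KDM5A knockout 33 with only the 2 groups and 1 with the span. The ZBTB7A call under C70 became 0 without centring, with only the 2 groups, over the wider set and with cyclic loess, and 3 with the span. The 2 ZBTB7A calls in the KDM5A knockout became 0 without centring and over the wider set, 18 with only the 2 groups, 36 with the span and 1 with cyclic loess. For the change at bound regions, no centring moves nothing by construction. At the same control width, the difference between regions with and without KDM5A, KDM5B and ZBTB7A was 0.088, 0.075 and 0.059 in the KDM5A knockout, 0.063, 0.039 and 0.074 in the KDM5B knockout, 0.029, 0.020 and 0.066 in the ZBTB7A knockout and 0.35, 0.32 and 0.35 under C70, so all of them turned from below 0 to above it. With the 2 control libraries kept apart for matching and measuring, the knockouts lay between -0.02 and 0.04 on average and C70 between 0.27 and 0.29. With a different control library for each contrast of a pair, the covariance of H3K4me3 width changes was 0.0388 for the KDM5A and KDM5B knockouts, 0.0289 for the KDM5A and ZBTB7A knockouts and 0.0310 for the KDM5B and ZBTB7A knockouts, lower than with shared controls and still above 0.

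The labels give replicate numbers but do not say whether these pair the samples. Correlations of same-numbered deviations ran from -0.16 to 0.20 for H3K4me3, -0.055 to 0.14 for KDM5A, -0.014 to 0.32 for KDM5B and -0.19 to 0.043 for ZBTB7A. With the replicate block, H3K4me3 calls were 66 in the KDM5A knockout and 99 in the ZBTB7A knockout, of which 59 and 86 were called without it. KDM5A calls in the ZBTB7A knockout were then 2, and ZBTB7A calls 0 under C70 and 1 in the KDM5A knockout. The exact tests in the block changed no call.

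Leaving out each library in turn leaves 1 library in a group, which is then assumed to vary like the others, and raises the counts of gained and lost regions by construction. The exact p of H3K4me3 peak number ranged from 0.0476 (without KDM5B knockout replicate 1) to 0.152. That of H3K4me3 width ranged from 0.0190 to 0.0667, that of KDM5A width from 0.0190 to 0.0667, and that of ZBTB7A width from 0.0190 (without control replicate 1) to 0.733. H3K4me3 regions gained and lost ranged over 2667 to 4631 and 35 to 153 in the KDM5A knockout, 2640 to 4805 and 9 to 107 in the KDM5B knockout, and 1714 to 3288 and 44 to 302 in the ZBTB7A knockout, and 142 to 324 were lost under C70. For KDM5A they ranged over 347 to 3078 and 1307 to 5765 in the KDM5B knockout, 87 to 667 and 3598 to 10081 in the ZBTB7A knockout, and 1016 to 2697 and 1073 to 4872 under C70. For KDM5B they ranged over 307 to 3182 and 6523 to 15243 in the KDM5A knockout, 289 to 3970 and 5720 to 15077 in the ZBTB7A knockout, and 2291 to 5152 and 3660 to 8655 under C70. For ZBTB7A they ranged over 466 to 6356 and 1820 to 12680 in the KDM5A knockout, 4361 to 18867 and 96 to 3418 in the KDM5B knockout, and 1509 to 11385 and 710 to 8461 under C70. The balance turned to gains for KDM5A in the KDM5B knockout without its replicate 2 (3078 gained and 1307 lost). Leaving out control replicate 2 turned the balance to losses for KDM5A and ZBTB7A under C70. For KDM5B under C70 the balance turned to gains without control replicate 1 or either C70 library, and for ZBTB7A in the KDM5A knockout without control replicate 1 or knockout replicate 2.

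Width calls for H3K4me3 ranged from 12 to 585 in the KDM5A knockout, 7 to 573 in the KDM5B knockout and 30 to 610 in the ZBTB7A knockout, highest without control replicate 1 and lowest without a library of the knockout itself. They were 80 and 79 in the KDM5A and KDM5B knockouts without control replicate 2. In the KDM5A knockout they were 85 without either KDM5B knockout library and 98 without ZBTB7A knockout replicate 1, in the KDM5B knockout 70 without either KDM5A knockout library, and in the ZBTB7A knockout 97 without either KDM5B knockout library. KDM5A calls ranged from 0 to 96 in the KDM5B knockout (96 without its replicate 1) and 0 to 179 in the ZBTB7A knockout (0 without either control or C70 library, 38 and 31 without KDM5B knockout replicates 1 and 2, 179 and 60 without its own). KDM5B calls ranged from 0 to 75 in the KDM5A knockout (75 without its replicate 1, 8 and 19 without ZBTB7A knockout replicates 1 and 2) and 0 to 125 in the ZBTB7A knockout (0 without either control library, 12 without either C70 library, 61 and 86 without KDM5A knockout replicates 1 and 2, 125 without its replicate 1). ZBTB7A calls ranged from 0 to 69 in the KDM5A knockout (69 without its replicate 2, 0 without control replicate 2) and 0 to 3 in the KDM5B knockout (3 without control replicate 1), and were 0 under C70 without any 1 library. Of H3K4me3 regions 78.1% to 90.0% overlapped KDM5A, 59.6% to 76.1% KDM5B and 77.2% to 92.8% ZBTB7A. Of KDM5A regions 63.5% to 85.4% overlapped H3K4me3, 60.5% to 84.8% KDM5B and 76.1% to 94.8% ZBTB7A. Of KDM5B regions 43.0% to 54.2% overlapped H3K4me3, 48.2% to 72.3% KDM5A and 63.6% to 82.3% ZBTB7A. Of ZBTB7A regions 32.4% to 50.1% overlapped H3K4me3, 33.1% to 64.3% KDM5A and 33.9% to 68.4% KDM5B. The H3K4me3 difference at bound regions in the KDM5A knockout ranged from -0.22 to -0.12 for KDM5A and for KDM5B and from -0.23 to -0.13 for ZBTB7A, on the log2 scale. The preset gene lists were not run, since no annotation of hg19 was used here.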

Other observations

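The tests on the KDM5B regions lost in the KDM5A knockout and on regions beside peak-free stretches were chosen only after the results had been seen, and cyclic loess normalization was added after seeing the data with its bound set before its result. H3K4me3 domains of control cells were broader the more of the 3 proteins they carried. The median width was 628 bp at the 1533 regions with none, 1013 bp at the 2579 with 1 (13.6%), 1606 bp at the 4433 with 2 (23.4%) and 2190 bp at the 10433 with all 3. This is a description across regions, and wider regions also overlap more peaks by their length alone.

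The KDM5B regions lost in the KDM5A knockout are described here by presence of ZBTB7A. Kept KDM5B regions were not split in this way, so the differences may not be particular to the lost regions. The 2643 without ZBTB7A were narrow (median 347 bp), 11.7% carried H3K4me3, 60.8% were called in at least 1 KDM5B library under C70 and 24.9% in both. The 3073 with ZBTB7A had a median of 630 bp, 79.7% carried H3K4me3, 93.0% were called in at least 1 C70 library and 76.3% in both. Libraries of the ZBTB7A knockout gave the reverse order. Of the regions without ZBTB7A, 73.1% were called in at least 1 of them and 23.2% in both, against 40.5% and 5.47% of those with it. H3K4me3 regions called in exactly 2 libraries did not single out the knockouts. The 2 libraries of the KDM5A, KDM5B and ZBTB7A knockouts held 101, 55 and 72, above the median of 16 over the 32 pairs of libraries from different groups, but KDM5A and KDM5B knockout replicates 2 held 194 together, KDM5B and ZBTB7A knockout replicates 2 held 73, and the C70 library with KDM5B knockout replicate 2 held 261.

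H3K4me3 regions were gained far more often than lost, and widened more often than they narrowed, in all 3 knockouts. For the wider regions alone, a width shift that follows region size is argued against as the whole cause. After cyclic loess at least 80.9% as many wider regions passed in each knockout (142 wider and 29 narrower, 120 and 11, and 123 and 22). Narrower calls rose from 12, 1 and 10, so the imbalance became smaller. Cyclic loess acts on regions called in every fitted library, so it does not bear on gained and lost regions. Presence of the lost protein at the gained sites as a common cause is not decided. Compared with kept regions of the same width range, the difference in share was -11.6 percentage points for KDM5A in its knockout (19.2% against 30.8%). It was -2.94 for KDM5B and 6.19 for ZBTB7A, each in its own knockout. By definition kept regions carry H3K4me3 in control cells and gained regions do not, and 82.8% of control KDM5A regions overlapped the mark. This selection lowers the KDM5A share of gained regions in advance. The KDM5A difference was also -11.3 points in the KDM5B knockout and -15.7 in the ZBTB7A knockout. A shortage of weak peaks called in the control libraries stays open: at a −log10 q of at least 20 in both libraries 68, 32 and 24 regions were gained and 1, 1 and 0 lost, against at most 1, 1 and 4 in the crossed splits, which met the bound set beforehand, but each side of a crossed split holds 1 control library and stays low under such a shortage too, and read counts were not used here. A biological response of H3K4me3 common to the knockouts may therefore exist, and cannot be told apart from that shortage with these lists.

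KDM5B regions without ZBTB7A were lost more often in the KDM5A knockout. The difference was not confined to weak peaks: between regions with and without ZBTB7A it was -12.3 percentage points or further below 0 in every quartile of control −log10 q. Whether the short list of replicate 2 contributed is not decided. With replicate 1 alone the difference was -24.3, against -20.0 with both. A lost region is absent from replicate 1 too, so leaving out replicate 2 can hardly remove a loss. A longer list of replicate 2 might have held some of these regions. Binding of the KDM5B antibody to KDM5A stays open. Regions with KDM5A were lost less often over all (-10.8 points) and in the 2 stronger quartiles (-32.7 and -16.0). In the weakest quartile they were lost more often (39.6% against 27.6%, 11.9 points). A region that also holds KDM5B can keep a peak after KDM5A is lost, so these counts cannot decide the question. Peaks particular to the control libraries are argued against only in part. Of the lost regions without ZBTB7A, 73.1% were called in a KDM5B library of the ZBTB7A knockout, mostly in replicate 1 (71.4%, and 24.9% in replicate 2). Replicate 1 of that knockout and control replicate 1 held 1276 KDM5B regions called in exactly these 2 libraries, 17.8% of them with ZBTB7A. This was the highest count of the 24 pairs of KDM5B libraries from different groups, whose median was 150. The lost regions without ZBTB7A were seldom called in both libraries of another group, 23.2% in the ZBTB7A knockout and 24.9% under C70, where KDM5A had not been knocked out. Irregular calling of these regions from library to library therefore stays open, and a dependence of KDM5B on KDM5A away from ZBTB7A is not established; differences between cultures or precipitations were not tested.

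The strongest gained and lost regions often lay beside the largest peak-free stretch of a chromosome, which is the assembly's centromere gap on most chromosomes but not on the X chromosome (123098148 to 128655516). Of the 78 entries of named regions over all contrasts, 29 (37.2%) lay within 2 Mb of such a stretch, against 2.19% of all 40276 entries of gained and lost regions, a ratio of 16.9. With regions that recur between contrasts counted once, these were 19 of 67 (28.4%), against 2.25% of 25941, a ratio of 12.6. Only 1 of the 19 was named for more than 1 antibody. Reads from repeated sequence beside centromeres are a candidate explanation for these regions, including the chromosome 17 region gained in every knockout. No biological explanation was tested, and copy number was not analysed here.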
